A study of Mus musculus with 10 samples.

How the data were processed

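RNA was measured in 10 cell lines. Per the labels' protocols, cDNA was made with SMART-Seq v4 reagents from 1 ng of total RNA, sheared, and made into libraries with a ThruPLEX kit. The deposited table holds whole-number counts per gene for 10 libraries, 1 column each, and its values are whole numbers with a different total in each column, so they were taken as counts without normalization. The submitters' processing notes name STAR 2.5, Cufflinks 2.2.1, DESeq2 and the mouse build mm9. The role of each tool, the gene annotation and the strand setting are not given in the sources used here.

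The table held 12824 rows. In 18 of them a bare number stood in place of a gene name. These rows, 0.332 to 0.491% of the counts of a library, were left out of library sizes and tests. Of the remaining 12806 genes, 12765 names matched a mouse symbol. The lowest row total was 7 and 12363 rows had a count in all 10 libraries. The rule by which the authors kept genes in the deposited table is not given in the sources used here. No 2 libraries were identical. The reference tables used here are of GRCm38.p6, another build than the authors'. They served for names, for which genes share a chromosome and for the order of neighbouring genes. GC content came from reference transcripts, and no coordinates are given. Without a stated strand setting, overlapping and antisense genes cannot be told apart.

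Groups came from the sample titles. No label says whether the lines of a group came from separate mice, so p-values measure the spread between these lines. No batch is named in the labels.

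Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit with robust dispersion, glmQLFTest), with Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the root of the F statistic. CPM were computed from the deposited counts with TMM scaling over all 10 libraries, and means are given with the SD. The knockdown was tested in the 8 metastatic lines, the site in all 10 lines with the knockdown as a covariate, and their interaction in a fit of 4 groups. The primary pair was described by log2 ratios of CPM with a prior count of 2 and was not tested. Counting intervals are exact binomial at 95%; no molecular identifiers are named in the sources used here, so intervals and floors cover counting error only.

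30 gene lists were fixed before the data were examined. Lists with at least 5 tested members entered camera (limma 3.58.1) with a preset correlation of 0.01, camera with an estimated correlation, and fry, whose one-way test does not compare a list with other genes. No list passed camera with an estimated correlation in either comparison. The fibroblast, immune, endothelial and lung epithelial lists had too few members to test, and no gene of the mitochondrially encoded list was in the table. The sex-linked list was only read per library.

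Named genes followed a rule fixed before the data were examined. It took Trp53 and Birc5, the 12 largest changes each way in the knockdown comparison, the 10 each way between sites and the 5 each way in the primary pair. The first 2 sets needed an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, and gene models without a proper name were left out. Up to 4 called members were named per list, or the 2 with the highest CPM. Some genes this rule took are not reported here. Rn45s and the 18 rows without a gene name fall outside this rule.

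Alternatives were DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0, limma voom with quality weights, other low-count filters, no robust dispersion, a 1.5-fold threshold, other sets of lines and leaving out each line. Thinning to the smallest library and a term for line numbers 376 to 378 were added after the data were seen.

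The scripts were tested on simulated data with 200 changed genes. For the knockdown comparison, with 11972 genes, 60 of 66 genes changed 4-fold, 37 of 67 changed 2-fold and 8 of 65 changed 1.5-fold were recovered, and 3 unchanged genes were called. For the site comparison, with 12650 genes, 49 of 64 genes changed 4-fold, 19 of 66 changed 2-fold and 6 of 64 changed 1.5-fold were recovered, and 4 unchanged genes were called. For the interaction, with 12669 genes, 23 of 66 genes changed 4-fold and 0 of 67 changed 2-fold were recovered, and 5 unchanged genes were called.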

Results

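RNA-seq gene counts were read for 10 cell lines of mouse esophageal squamous cell carcinoma, a cancer of the lining of the esophagus, that carry a mutant Trp53 allele. Each line had received a control short hairpin RNA (shCtrl) or a hairpin against Trp53 (shTrp53), which lowers the mutant transcript. There was 1 primary line of each kind. The other 8 lines were grown from lung metastases harvested at week 8 and sorted for the fluorescent protein YFP, 5 of them shCtrl (line numbers 376, 377, 378, 382 and 383) and 3 shTrp53 (384, 386 and 387). Total counts were 15317280 in the shCtrl primary line, 11057049 in the shTrp53 primary line, 11644562 to 14214802 in the 5 shCtrl metastatic lines and 14055576, 15917672 and 18431216 in shTrp53 metastatic lines 384, 386 and 387.

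Trp53, the targeted gene, was low in every shTrp53 library. It stood at 94.5 to 131 CPM (counts scaled to library size) in the 5 shCtrl metastatic lines and at 5.16 to 7.36 CPM in the 3 shTrp53 metastatic lines. Trp53 fell by 4.18 on the log2 scale (SE 0.19, adjusted p = 3.45e-06, edgeR quasi-likelihood test). In the primary pair Trp53 was at 73.8 CPM with shCtrl and 6.54 CPM with shTrp53, a log2 ratio of -3.47 with a 95% counting interval of -3.84 to -3.17.

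Birc5 encodes survivin, an inhibitor of apoptosis and a member of the chromosomal passenger complex, and it is named in the title of the series. Birc5 fell by 1.41 on the log2 scale in the shTrp53 metastatic lines (SE 0.27, adjusted p = 0.00787, edgeR quasi-likelihood test), from 306 ± 93.7 CPM (SD, n = 5) to 115 ± 32.2 CPM (SD, n = 3). Every shTrp53 metastatic line, at 78.2, 128 and 139 CPM, lay below every shCtrl metastatic line. The shCtrl lines 376, 377, 378, 382 and 383 stood at 442, 342, 297, 254 and 194 CPM, lower with each higher line number. The shTrp53 metastatic lines carry the highest line numbers, so the knockdown and line order cannot be told apart for this gene. With a term for line numbers 376 to 378, added after the data were seen, the fall of Birc5 was 0.96 (SE 0.25, adjusted p = 0.0462). Tested against a 1.5-fold change, the Birc5 log2 fold change had an adjusted p of 0.0572. In the primary pair Birc5 was at 360 CPM with shCtrl and 272 CPM with shTrp53, a log2 ratio of -0.40 with a 95% counting interval of -0.47 to -0.34.

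**Figure D1:**
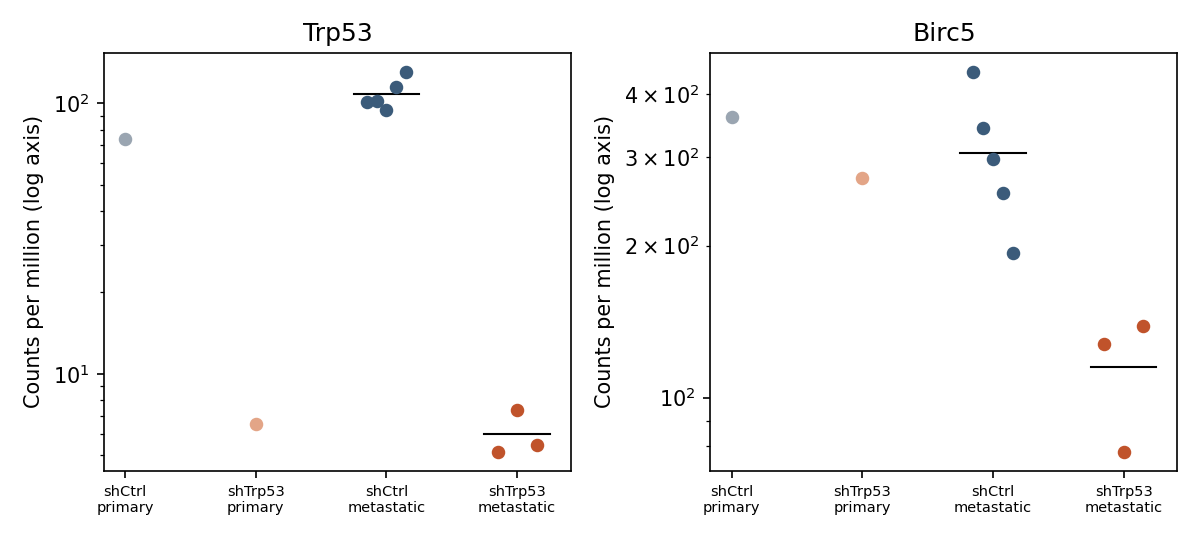
Levels in CPM of Trp53 and Birc5 (log axis) in each library, 1 point per line, by group, with a bar at the mean of the metastatic groups. The 3 shTrp53 metastatic lines lie below the 5 shCtrl metastatic lines for both genes.

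The first comparison set shTrp53 (n = 3) against shCtrl (n = 5) metastatic lines. The shTrp53 lines carry the highest line numbers, and genes of whole chromosomes were shifted between the groups. An effect of lowering mutant Trp53 therefore cannot be told apart from line order or another difference between the groups of lines. Of 12120 genes tested, 2634 changed, 1326 higher and 1308 lower in the shTrp53 lines. Of the genes with a proper name, a mean of at least 5 CPM and no overlap between the groups, those with the largest rises included Tslp, a cytokine made by epithelial cells, from 14.1 ± 13.3 to 136 ± 104 CPM (log2 fold change 3.27, SE 0.67, adjusted p = 0.0103), and Marveld3, a tight junction protein, from 1.23 ± 0.501 to 24.1 ± 11.4 CPM (4.28, SE 0.37, adjusted p = 0.000168). Nup62cl rose from 1.04 to 47.7 CPM, Tnfrsf26 from 0.963 to 37.8 CPM, Prl3d1 from 0.360 to 19.4 CPM, Smoc2 from 2.31 to 31.8 CPM and Bglap3 from 7.11 to 128 CPM. Bglap3 has near-identical neighbours with which it could share reads. Hgfac, Arhgap9, Usp18, Fcmr and Plekha2 also rose, with log2 fold changes of 6.84, 6.17, 5.15, 4.02 and 3.43. Single lines set some of these means. Without line 386 the shTrp53 mean was 14.6 CPM for Smoc2, 31 CPM for Nup62cl, 7.59 CPM for Hgfac (13.4 CPM with it) and 9.93 CPM for Fcmr (16.3 CPM with it). It was 12 CPM for Usp18 without line 384 (29.6 CPM with it) and 77.6 CPM for Tslp without line 387. The shCtrl mean was 8.54 CPM for Tslp and 0.552 CPM for Tnfrsf26 without line 382, 0.209 CPM for Prl3d1 without line 383 and 0.083 CPM for Arhgap9 without line 376 (0.178 CPM with it).

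By the same limits, the largest falls included Crabp1, a retinoic acid binding protein, from 308 ± 46.2 to 16.0 ± 19.6 CPM (log2 fold change -4.27, SE 1.01, adjusted p = 0.0164), and Vim, an intermediate filament protein of mesenchymal cells, from 38.0 ± 20.8 to 2.52 ± 3.41 CPM (-3.95, SE 0.85, adjusted p = 0.0119). Ccl2, which attracts monocytes, fell from 97.1 to 6.28 CPM and Csf1, a growth factor of macrophages, from 82.6 to 11.9 CPM. Krt20 fell from 42.9 to 4.15 CPM, Ldhb from 10.3 to 1.16 CPM and Casq2 from 13.9 to 1.56 CPM. Stmn2, C1qtnf3, Hist1h1b and Hist1h2ak fell with log2 fold changes of -3.34, -3.15, -2.73 and -2.68, and the histone genes belong to a family whose copies can share reads. Without line 384 the shTrp53 mean was 5.11 CPM for Crabp1, 0.556 CPM for Vim, 3.46 CPM for Ccl2, 0.338 CPM for Stmn2 (0.99 CPM with it) and 0.908 CPM for C1qtnf3 (1.37 CPM with it). The shCtrl mean of C1qtnf3, 12.2 CPM, was 5.89 CPM without line 378. Of the 25 genes named here by rule, 22 passed whichever line was left out. The exceptions, by the edgeR test, were Crabp1, C1qtnf3 and Hist1h2ak, which missed the threshold without shTrp53 metastatic replicate 386 (adjusted p = 0.0657, 0.0944 and 0.0595). C1qtnf3 and Hist1h2ak also missed it without 384, and C1qtnf3 without 387.

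The count depended on the lines in the fit. It was 1522 without shCtrl metastatic replicate 377, 1690 without 378, 1154 without shTrp53 metastatic replicate 384 and 1172 without 386, and 981 with the term for line numbers 376 to 378, of which 856 were among the 2634. With that term, of the genes named by rule, Usp18, Tslp, Crabp1, Vim, Stmn2, C1qtnf3 and Hist1h2ak missed the threshold, with adjusted p from 0.0569 for Usp18 to 0.199 for C1qtnf3. Of the 75 called genes taken from lists by rule, 41 passed whichever line was left out. Tested against a 1.5-fold change, 330 genes passed.

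Mitosis genes were lower in the shTrp53 metastatic lines. Of the 26 members of the chromosomal passenger and mitosis list, 24 fell and none rose, with a median log2 fold change of -1.07, and 26 fell when adjusted over the list alone. Top2a, a topoisomerase, fell from 296 to 142 CPM (log2 fold change -1.06), Cenpe, a kinetochore motor, from 108 to 46.5 CPM (-1.21), Ccna2, a cyclin, from 223 to 117 CPM (-0.93) and Cdc25c, a phosphatase that acts at mitotic entry, from 68.2 to 32.04 CPM (-1.08). The list passed the camera test (adjusted p = 2.23e-13), with an adjusted p = 0.654 with an estimated correlation. Its median relative to the mean of all 10 libraries was 0.422 to 0.566 in shCtrl lines 376 to 378. It was -0.0144 and -0.0592 in shCtrl lines 382 and 383 and -1.05 to -0.568 in the shTrp53 metastatic lines. The knockdown and line order therefore cannot be told apart for this list. Of 24 DNA replication genes 6 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.0344, adjusted p = 0.746 with an estimated correlation). Relative to the mean of all 10 libraries, this list's median was -0.423 in shCtrl line 383, below the shTrp53 metastatic lines (-0.37 to -0.304). It was -0.207 in shCtrl line 382 and 0.131 to 0.354 in lines 376 to 378. Rrm1 fell from 365 to 211 CPM, and Cdt1, a licensing factor, rose from 84.1 to 126 CPM. The replication list passed in 3 of the 8 fits that left out 1 line. It missed the threshold without 376, 377, 378, 384 or 387 (highest adjusted p = 0.126, without 387), and its direction turned with the term for line numbers 376 to 378 (adjusted p = 0.910). Rrm1 missed the threshold without 384 (adjusted p = 0.0501).

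Interferon response genes were higher in the shTrp53 metastatic lines. Of 21 measured members 12 rose and none fell (13 adjusted over the list alone), with a median log2 fold change of 2.10 (camera adjusted p = 6.13e-06, adjusted p = 0.746 with an estimated correlation). Usp18, which removes the ubiquitin-like protein ISG15, rose from 0.836 to 29.6 CPM, Irf9, a transcription factor of the interferon response, from 4.76 to 30 CPM and Ifit1 from 0.426 to 6.19 CPM. Relative to the mean of all 10 libraries, the list's median stood at 2.15 in line 384, 1.20 in line 386 and -0.10 in line 387, against -0.74 to -0.18 in the 5 shCtrl metastatic lines. The list passed in each of the 8 fits that left out 1 line, as did the mitosis, epithelial junction, mesenchymal, sterol and hypoxia lists. Without line 384 the shTrp53 mean of Usp18 was 12 CPM, and without line 386 that of Ifit1 was 3.76 CPM. Usp18 and Irf9 missed the threshold with the term for line numbers 376 to 378.

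Part of the epithelial junction list rose and part of the mesenchymal list fell. Of 17 epithelial junction members 6 rose and none fell (6 adjusted over the list alone, camera adjusted p = 0.000408, adjusted p = 0.59 with an estimated correlation). Cdh1, which encodes E-cadherin, rose from 35.5 ± 6.32 to 96.0 ± 8.90 CPM, Ocln, a tight junction protein, from 2.40 to 21.8 CPM and the simple epithelial keratins Krt8 and Krt18 from 67.6 to 267 CPM and from 294 to 1106 CPM. In the GRCm38.p6 annotation Ocln and Cdh1 lie on 2 chromosomes whose genes were higher as a whole in the shTrp53 metastatic lines, by medians of 0.33 and 0.31 on the log2 scale relative to all genes. Of the other genes named in this comparison, Prl3d1, Polk, Hmgcs1, Ctsl, Erap1 and Sdha lie on the first and Marveld3, Plekha2, Cdt1, Osgin1, Hmox1, Psmb10, Fgfr1, Itgb1 and Cox4i1 on the second. Hist1h1b and Hist1h2ak were not placed on a chromosome by their names, so they are in neither set. Of 17 mesenchymal members 6 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0181, adjusted p = 0.572 with an estimated correlation). Acta2, a smooth muscle actin, fell from 430 to 91.3 CPM, Tagln from 10.7 to 2.65 CPM and Zeb1, a repressor of epithelial genes, from 3.39 to 0.236 CPM. Without line 384 the shTrp53 mean of Zeb1 was 0.139 CPM.

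The lists of sterol synthesis, hypoxia and glycolysis, and NRF2 targets were lower. Of 24 sterol synthesis genes 11 fell and none rose, also when adjusted over the list alone (median -0.73, camera adjusted p = 0.000113, adjusted p = 0.746 with an estimated correlation), among them Hmgcs1 from 549 to 164 CPM, Cyp51 from 468 to 195 CPM and Srebf2 from 69.8 to 38.8 CPM. Relative to the mean of all 10 libraries, the sterol list's median was -0.40 and -0.45 in shCtrl lines 382 and 383, in the range of the 3 shTrp53 metastatic lines (-0.69 to -0.35), and 0.28 to 0.75 in lines 376 to 378. Of 20 hypoxia and glycolysis genes 6 fell (8 adjusted over the list alone, camera adjusted p = 0.0181, adjusted p = 0.687 with an estimated correlation), among them Aldoa from 725 to 386 CPM and Gpi1 from 249 to 149 CPM. Of 18 NRF2 targets 8 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0181, adjusted p = 0.746 with an estimated correlation). On the same relative scale the NRF2 list's median was -0.389 in shCtrl line 383, as in shTrp53 line 384, and 0.0653 to 0.303 in the other shCtrl metastatic lines. Slc7a11, a cystine transporter, fell from 183 to 74.6 CPM, while Hmox1, which degrades heme, rose from 47.6 to 97.4 CPM and Osgin1 from 9.79 to 33.8 CPM. With the term for line numbers 376 to 378 these lists did not pass. The adjusted p was then 0.1525 for the list sterol synthesis, metastatic knockdown, 0.0533 for the list hypoxia and glycolysis, metastatic knockdown, and 0.2599 for the list NRF2 targets, metastatic knockdown. The NRF2 list also missed the threshold without shTrp53 metastatic replicate 386 (adjusted p = 0.0932). Cyp51 and Hmox1 missed it without 384 or 387 (highest adjusted p = 0.0586 and 0.0688), and Slc7a11 and Hmox1 with the term for line numbers 376 to 378.

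**Figure D2:**
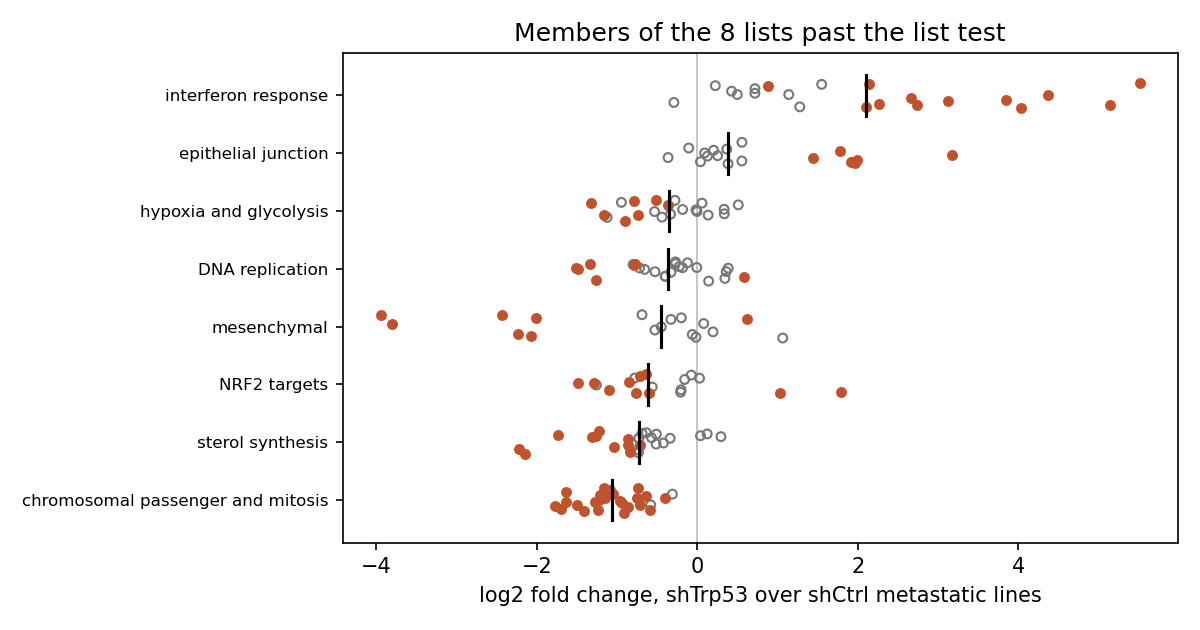
Log2 fold change of shTrp53 over shCtrl metastatic lines for each measured member of the 8 lists that passed the camera test. Filled points passed the edgeR test over all genes, open points did not, and the bar is the list's median, from -1.07 for mitosis to 2.10 for the interferon response.

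The other 16 lists did not pass the camera test, and their counts adjusted over the list alone follow those over all genes. Of 28 targets of wild-type p53, 2 rose and 1 fell (0 and 0 adjusted over the list alone, adjusted p = 0.651). Polk and Pmaip1 rose with log2 fold changes of 0.71 and 0.83, and Sesn1 fell by 0.77 on the log2 scale. Of 10 inhibitors of apoptosis Bcl2l1 and Cflar rose, with log2 fold changes of 0.76 and 0.55, and Birc5 fell (3 and 1, adjusted p = 0.68). Of 17 pro-apoptotic genes Bad and Pmaip1 rose and Casp8 fell (1 and 0, adjusted p = 0.595). Of 14 squamous basal genes Pdpn rose and 2 fell, among them Krt5, a basal keratin, from 915 to 279 CPM (1 and 2, adjusted p = 0.38). With the term for line numbers 376 to 378 the list squamous basal, metastatic knockdown, passed (adjusted p = 0.04965). Of 13 squamous differentiation genes Ivl, Sprr1b and Lor rose and Krt6a fell (4 and 1, adjusted p = 0.527). Many of these calls ended when 1 line was left out. Pmaip1, Sesn1 and Casp8 missed the threshold without 376, 377, 378, 384, 386 or 387 (highest adjusted p = 0.148, 0.134 and 0.176), Cflar without 376, 377, 378, 383, 384 or 386 (0.205) and Lor without 376, 377, 378, 382, 384 or 386 (0.176). Krt6a missed it without 376, 384, 386 or 387 (highest adjusted p = 0.112), Polk without 377, 384 or 387 (0.0679), Bad without 377 or 384 (0.093) and Krt5 without 384 or 386 (0.0507). With the term for line numbers 376 to 378 all of these but Krt6a missed it, as did Pdpn.

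Of 11 class I antigen presentation genes H2-D1, which has near-identical relatives, rose and 4 fell, among them Erap1 and Psmb10 (1 and 5, adjusted p = 0.457). Of 17 cytokines and chemokines Tslp rose and 4 fell, among them Csf1, Ccl2 and Tnf (3 and 5, adjusted p = 0.457). Tnf, at 2.25 CPM in the shCtrl metastatic lines, had 0 counts in the 3 shTrp53 metastatic lines and was at least 36.3-fold lower against a floor of 3 counts over the group. Hsp90b1 alone fell of 18 unfolded protein response genes (0 and 1, adjusted p = 0.516), and Tgfb2 alone of 16 YAP targets (0 and 1, adjusted p = 0.457). Of 17 TGF-beta response genes Smad6 rose and 2 fell, among them Tgfb2 (1 and 2, adjusted p = 0.457), and of 10 integrins Itgb1 rose and Itgb6 fell (1 and 1, adjusted p = 0.457). Of 24 matrix and protease genes 4 rose and 4 fell (4 and 4, adjusted p = 0.68), with Timp1, an inhibitor of metalloproteinases, falling from 97.7 to 27 CPM and the cathepsins Ctsb and Ctsl rising from 756 to 1312 and from 773 to 1268 CPM. Fgfr1 alone rose of 17 growth factor receptors and ligands (1 and 0, adjusted p = 0.702). Of 12 Wnt and Notch targets Lef1 and Myc rose and Jag2 fell (2 and 1, adjusted p = 0.516), and of 12 immediate early genes Jun fell (0 and 0, adjusted p = 0.957). Of 20 oxidative phosphorylation genes 3 rose, among them Cox4i1 and Sdha, and 5 fell, among them Atp5b and Uqcrc1 (3 and 7, adjusted p = 0.68). Signs differed within 3 of these lists: the medians of inhibitors of apoptosis and squamous differentiation were below 0 with means and tests above, and the median of immediate early genes was above 0 with a mean and test below. Among the genes named, Myc missed the threshold without 376, 377, 378, 384, 386 or 387 and Lef1 without 377, 378, 382, 384, 386 or 387 (highest adjusted p = 0.157 for both). Jag2 missed it without 376, 377, 378, 384 or 387 (highest adjusted p = 0.15), H2-D1 and Psmb10 without 377, 378, 384 or 386 (0.0964 and 0.116) and Jun without 377, 382, 386 or 387 (0.11). Erap1 and Itgb6 missed it without 384 or 386 (highest adjusted p = 0.0799 and 0.0879), Hsp90b1, Itgb1 and Sdha without 386 (0.0592, 0.0737 and 0.0509) and Ctsl and Uqcrc1 without 384 (0.0528 and 0.0581). With the term for line numbers 376 to 378 all of these but Jun and Itgb6 missed it.

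Markers of other cell types were few and were not tested as lists. Of 3 measured fibroblast markers, 1 endothelial marker and 3 lung epithelial markers none passed the threshold. The fibroblast markers had a median log2 fold change of -0.545. Of 3 measured immune markers Cd14 fell, from 9.86 to 4.97 CPM, and missed the threshold without 376, 377, 378, 384, 386 or 387 (highest adjusted p = 0.136) and with the term for line numbers 376 to 378. No mitochondrially encoded gene of the list was in the table.

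The second comparison asked how metastatic lines differed from primary lines, with the knockdown as a covariate. Of 12754 genes tested, 897 were higher and 966 lower in the 8 metastatic lines. The unfolded protein response had the lowest camera p of the lists, with 12 of 18 members higher and none lower (13 adjusted over the list alone, median 1.02, camera adjusted p = 2.98e-08, adjusted p = 0.329 with an estimated correlation). Atf4, a stress transcription factor, stood at 128 and 118 CPM in the primary lines and at means of 352 CPM in shCtrl and 335 CPM in shTrp53 metastatic lines. Asns, which makes asparagine, stood at 528 and 434 CPM against 1305 and 1086 CPM, and Trib3 at 20.9 and 16.2 CPM against 206 and 189 CPM. Atf4, Asns and Trib3 missed the threshold without the shTrp53 primary line (adjusted p = 0.0725, 0.115 and 0.119).

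Of the genes with a proper name, a mean of at least 5 CPM over the 10 libraries and no overlap between the sites, the 10 with the largest fitted rises were Cox6a2, Edn2, Soat2, Pdgfb, Car6, Rgn, Acox2, Klk11, Il1a and Cldn4. Car6, Rgn, Acox2, Klk11, Il1a and Cldn4 had log2 fold changes of 6.14, 5.79, 5.74, 5.39, 5.38 and 4.84. Cox6a2 had no counts in either primary line and was at least 61.3-fold higher in the metastatic lines against a floor of 3 counts over both. Edn2, Soat2 and Pdgfb had 2 counts or fewer in either primary line, and Acox2 had 0 and 9 counts. By the same limits, the largest falls were in Gpc3, a proteoglycan, at 31.9 and 32.4 CPM in the primary lines and below 0.3 CPM on average in both metastatic groups (-7.77, SE 0.61, adjusted p = 0.000156), and in Vim (-5.52), Itga1 (-5.41), C1qtnf3 (-5.29), Aldh3a1 (-4.76), Mgll (-4.13), Rhox5 (-4.00), Aff3 (-3.96), Sostdc1 (-3.88) and Serpini1 (-3.86).

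Epithelial junction genes were also higher, 8 of 19 (camera adjusted p = 1.05e-05, adjusted p = 0.315 with an estimated correlation), among them Epcam and Esrp1, and so were cytokines and chemokines, 7 of 20 with 1 lower (camera adjusted p = 0.00239, adjusted p = 0.491 with an estimated correlation), among them Cxcl16 with a log2 fold change of 2.83. Class I antigen presentation rose in 4 of 11 (camera adjusted p = 0.028, adjusted p = 0.526 with an estimated correlation), with H2-K1, which has near-identical relatives, at 1.83. Of wild-type p53 targets 8 rose and 1 fell (camera adjusted p = 0.0311, adjusted p = 0.526 with an estimated correlation), with Cdkn1a rising by 1.72 and Sesn1 falling by 2.15. Mitosis genes fell in 10 of 26 (camera adjusted p = 1.15e-06, adjusted p = 0.526 with an estimated correlation), DNA replication in 9 of 24 (camera adjusted p = 1.51e-05, adjusted p = 0.526 with an estimated correlation) and sterol synthesis in 5 of 24 (camera adjusted p = 2.34e-05, adjusted p = 0.554 with an estimated correlation). NRF2 targets fell in 7 of 18 with 1 higher (camera adjusted p = 0.00961, adjusted p = 0.566 with an estimated correlation), and of the mesenchymal list Vim and Zeb1 fell (camera adjusted p = 0.0331, adjusted p = 0.491 with an estimated correlation). Adjusted over the list alone, 19 mitosis, 10 replication, 16 sterol, 8 NRF2 and 4 mesenchymal genes fell, 1 NRF2 target rose, and 9 p53 targets rose and 2 fell. Some metastatic lines stood at the level of the primary lines. Relative to the mean of all 10 libraries, the mitosis list's median was 0.57 and 0.39 in the primary lines, 0.42 to 0.57 in shCtrl lines 376 to 378, -0.01 and -0.06 in 382 and 383 and -1.05 to -0.57 in the shTrp53 metastatic lines. The sterol list's median was 0.61 and 0.64 in the primary lines, 0.75, 0.42 and 0.28 in lines 376, 377 and 378 and -0.69 to -0.35 in the other 5 metastatic lines. For p53 targets line 376, at -0.23, was as low as the primary lines, at -0.31 and -0.23. For epithelial junction genes line 378, at -0.28, was below the shTrp53 primary line, at -0.19. For antigen presentation lines 386 and 387, at -0.56 and -0.33, were in or below the range of the primary lines, at -0.38 and -0.25. The counts adjusted over the list alone were 8 and 0 for epithelial junction, 7 and 1 for cytokines and 4 and 0 for antigen presentation. Without the shTrp53 primary line Esrp1, Cdkn1a, Vim and Zeb1 missed the threshold (adjusted p = 0.0996, 0.129, 0.0956 and 0.208).

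The other 14 lists did not pass the camera test in this comparison, and counts adjusted over the list alone again follow those over all genes. Of 17 TGF-beta response genes 1 rose and 6 fell, among them Bmp4, Tgfb3, Id2 and Id3 (1 and 6, camera adjusted p = 0.151). This list passed fry, which tests whether its genes moved one way (adjusted p = 0.0224). The mitosis, replication, sterol, NRF2 and p53 target lists, which passed camera, missed the threshold with fry (adjusted p from 0.0714 to 0.115). Of 17 growth factor receptors and ligands 4 rose, among them Egfr, Vegfc and Hbegf, and 1 fell (6 and 2, adjusted p = 0.0815). Of 14 squamous basal genes Krt17 and Pdpn rose and Krt15 and Sox2 fell (2 and 5, adjusted p = 0.471), and of 14 squamous differentiation genes Klf4, Sprr1b and Dsg3 rose (3 and 1, adjusted p = 0.161). Of 21 interferon response genes Ifi35 rose and Ifit2 fell (1 and 1, adjusted p = 0.161). Of 21 hypoxia and glycolysis genes 3 rose and 4 fell (3 and 4, adjusted p = 0.313), of 24 matrix and protease genes 1 rose and 4 fell (4 and 7, adjusted p = 0.752) and of 10 integrins Itgb6 rose and Itga1 and Itgb5 fell (2 and 3, adjusted p = 0.344). Birc3 rose and Bcl2 fell of 10 inhibitors of apoptosis (1 and 1, adjusted p = 0.609), and Pmaip1 and Bid rose and Casp6 fell of 17 pro-apoptotic genes (4 and 1, adjusted p = 0.584). Wwc1 rose of 16 YAP targets (0 and 0, adjusted p = 0.252) and Ier3 of 14 immediate early genes (1 and 0, adjusted p = 0.161). Lef1 fell of 13 Wnt and Notch targets (0 and 1, adjusted p = 0.902) and Ppargc1a of 21 oxidative phosphorylation genes (0 and 1, adjusted p = 0.595). The Wnt and Notch list had a median and mean above 0 and a test below, and the oxidative phosphorylation list a mean below 0 with a median and test above. Without the shTrp53 primary line all of the genes named from these lists but Bmp4, Krt15, Itga1, Birc3 and Lef1 missed the threshold (highest adjusted p = 0.398, for Pdpn). Without the shCtrl primary line Krt17, Sprr1b, Dsg3, Itgb6, Birc3, Bid, Casp6, Wwc1, Ier3 and Lef1 missed it (highest adjusted p = 0.298, for Dsg3). Dsg3 also missed it without 377, 378, 382, 384, 386 or 387, Birc3 without 377, 378, 382, 383, 386 or 387, Casp6 without 377, 378, 383, 386 or 387, Wwc1 without 382, 384, 386 or 387 and Pdpn without 382.

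Among markers of other cell types, Cd68 rose from 75 and 85.7 CPM in the primary lines to means of 117.5 and 133 CPM in the metastatic groups. Cd74 had 0 counts in both primary lines and was at least 19.7-fold higher in the metastatic lines against a floor of 3 counts over the pair. Dcn, the fibroblast marker that rose, was at 0.0648 and 0 CPM in the primary lines and at means of 4.21 and 2.95 CPM in the metastatic groups. None of 3 endothelial and 3 lung epithelial markers passed the threshold. The Y-linked Eif2s3y and Uty had 0 counts in all 8 metastatic lines and were at least 766-fold and 198-fold lower than in the primary lines, and Ddx3y, with 325 and 124 counts in the primary lines, had 1 count in line 383 and 0 in the other 7. Cd68 and Dcn missed the threshold when either primary line was left out (highest adjusted p = 0.17 and 0.23), and Cd74 when either primary line or 382, 384 or 387 was left out (0.206).

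This comparison rested on 2 primary lines, assumed to share the knockdown difference of the metastatic lines. The Y-linked genes also split the lines by site. Their summed counts were 797 in the shCtrl primary line, 346 in the shTrp53 primary line and at most 1 in any metastatic line. The genes and lists called here therefore cannot be told apart from a difference in the origin of the lines. Without the shTrp53 primary line 121 genes passed, and without shTrp53 metastatic replicate 387 1038 genes. Of the 20 genes named by rule, 9 passed whichever line was left out, as did 17 of the 80 named from lists. The other 11 of the 20 missed the threshold without the shTrp53 primary line, with adjusted p from 0.0533 for Aldh3a1 to 0.368 for Sostdc1, among them Cldn4 (0.144) and Vim (0.0956). Edn2, Car6, Rgn and Acox2 also missed it without the shCtrl primary line, and Edn2 without 382, 384 or 387. Class I antigen presentation (adjusted p = 0.443) and p53 targets (adjusted p = 0.0771) missed the threshold without the shCtrl primary line, and p53 targets, mesenchymal genes (adjusted p = 0.209) and NRF2 targets (adjusted p = 0.169) without the shTrp53 primary line. Antigen presentation also missed it without 376. Growth factor receptors and ligands passed without the shTrp53 primary line (adjusted p = 0.00451), without 384 and without 386, immediate early genes without the shTrp53 primary line (adjusted p = 0.00983) and interferon response genes without 387 (adjusted p = 0.00712). In the shCtrl lines alone, 5 against 1, 80 genes passed, and in the shTrp53 lines alone 1894.

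**Figure D3:**
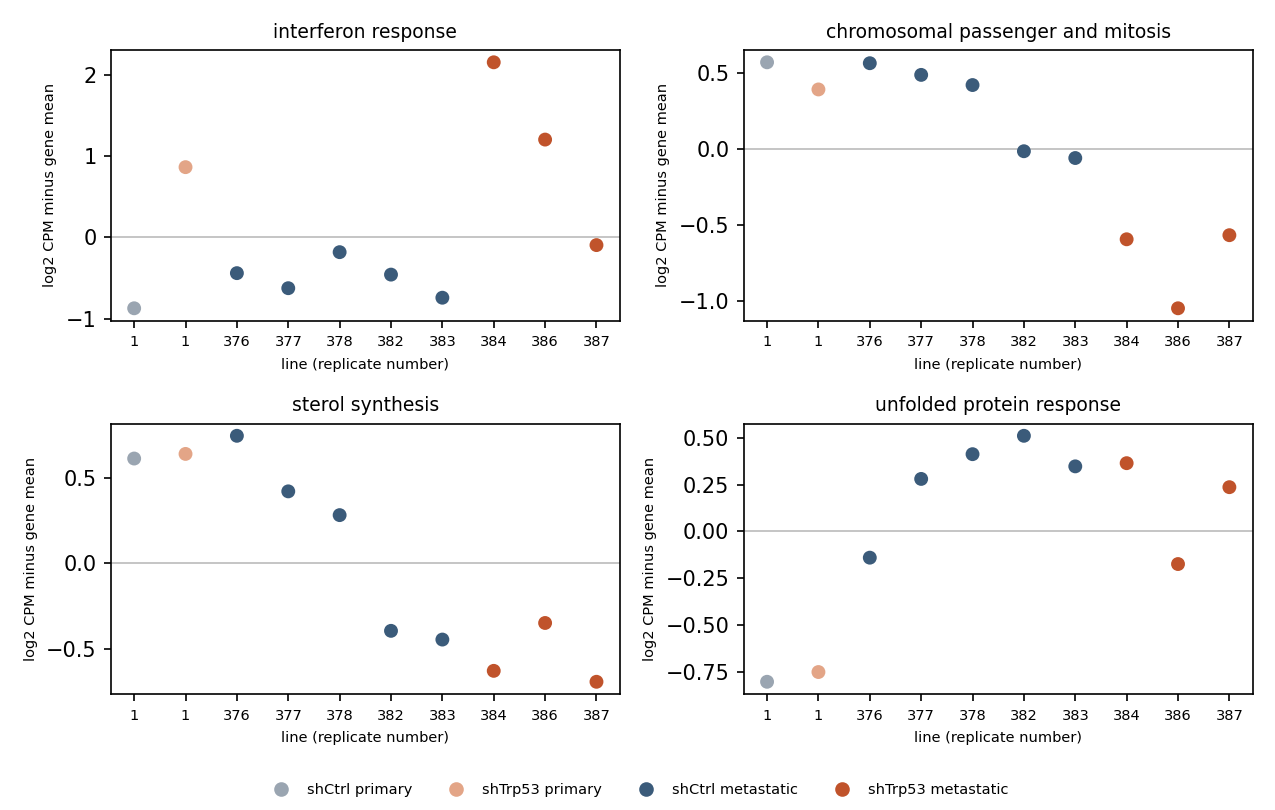
Median over list members of the log2 CPM minus the gene's mean over all 10 libraries, for 4 lists, with 1 point per library, coloured by group and labelled by line number. The unfolded protein response is lowest in the 2 primary lines, and the interferon response is highest in line 384, at 2.15.

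The third comparison asked whether the knockdown difference itself differed between metastatic and primary lines. No gene passed in edgeR (1168 genes had an unadjusted p under 0.05) and none with limma voom, and 52 passed with DESeq2. The primary arms had 1 line each, assumed to vary like the metastatic lines.

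Between the primary lines, which have no replicates, 274 of 8617 genes at 10 CPM or more in a line differed at least 2-fold, 230 higher and 44 lower with shTrp53. The largest ratios were those of Bglap3 (log2 ratio 4.09), Scg2 (3.15), Slc16a11 (2.83), Elmo3 (2.73), which lies on the chromosome that carries Cdh1, and Eya2 (2.71), and the lowest after Trp53 those of Krt20 (-3.08), Myl9 (-2.50), St3gal5 (-2.19) and Ncam1 (-2.09). Interferon response genes had a median log2 ratio of 1.82 and epithelial junction genes of 0.77, each at percentile 100 among 10000 random lists of the same size and expression. Mitosis genes had a median of -0.21, at percentile 14.3. Genes of a list can move together, unlike those of a random list, so these percentiles describe the pair and are not tests. Of the 2634 genes called in the metastatic comparison, 1763 had the same sign in the primary pair, 66.9% (95% binomial interval 65.1 to 68.7%, exact), against 52.9% of the genes tested and not called. Genes are not independent replicates, so the interval covers counting error only.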

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

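Both tests of the Y-linked pattern were chosen after the result was seen. In 188 values tested in the 5 shCtrl metastatic lines, 8 single lines lay far from the other lines. Chance alone gives about 5% of such tests, so the count of 8 is no more than chance alone would give. The count does not weigh how these values spread over the lines, and most were in line 376. In line 376 Rhox5 was at 7.77 CPM (others 0.667 to 1.93), Col4a1 at 9.66 CPM (3.05 to 4.59), Lef1 at 11 CPM (9.26 to 9.68) and Jag2 at 41.4 CPM (19.7 to 23.9), and Rn45s took 0.099% of the counts (0.048 to 0.058%). C1qtnf3 was at 37.3 CPM in line 378 (others 3.96 to 7.63) and Cflar at 142 CPM in line 382 (94.8 to 104). Ddx3y was at 0.0741 CPM, 1 count, in line 383 and at 0 in the other lines of the group.

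Of the 18 rows without a gene name, tested apart and adjusted over the 18, 3 were higher in the shTrp53 metastatic lines, with log2 fold changes of 0.45, 0.35 and 2.27, and 1 was lower.

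Ddx3y, Eif2s3y and Uty, which lie on the Y chromosome, had 325, 395 and 77 counts in the shCtrl primary line and 124, 162 and 60 in the shTrp53 primary line. In the 8 metastatic libraries they had 0 counts apart from the 1 count of Ddx3y. Depth is argued against, since at the lower primary level 364 counts of the 3 genes together were expected in the metastatic library where the fewest were expected. It stays open whether the metastatic lines may descend from cells that lost the Y chromosome or from cells that never had one, because the highest summed count was 1 and no other Y-linked gene was in the table. Xist, also on the sex-linked list, was not in the table. The rule by which genes were kept is not given, so its absence does not decide the question. The Y-linked difference follows the site, so genes and lists called between the sites may reflect the origin of the lines.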

How the results depend on the processing

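Across alternatives Trp53 fell and passed in every one tried. Thinning and the line-number term were chosen after seeing the data. Leaving out 1 line was followed for lists, for counts of genes higher or lower and for single genes other than Trp53 and Birc5. It left 1951 values on the same side of the threshold or, for counts, within 1.5 times. In 274 cases a result no longer passed, in 6 a result came to pass, and 13 counts moved by over 1.5 times. The number of genes called between shTrp53 and shCtrl metastatic lines ran from 1154 to 3239 when 1 line was left out. It was 330 against a 1.5-fold change, where fewer genes can pass, and 981 with the term for line numbers 376 to 378, which leaves 2 shCtrl lines in direct contrast. The Birc5 log2 fold change of -1.41 missed the threshold against a 1.5-fold change (adjusted p = 0.0572), where other alternatives gave adjusted p from 9.682e-06 to 0.04616. For metastatic against primary lines the count ran from 121 to 2678 when 1 line was left out, and was 2806 with DESeq2, 732 with limma voom and 80 in the shCtrl lines alone; the cause was not tested. With DESeq2 the interaction count was 52; the cause was not tested. The interaction could not be fitted without a primary line. Lists passing for the knockdown went from 8 to 5 with the line-number term, 4 with fry and 0 with an estimated correlation. With fry the lists interferon response (adjusted p = 0.0835), sterol synthesis (0.212), NRF2 targets (0.246) and DNA replication (0.353) missed the threshold for the knockdown. For the site, lists passing went from 10 to 6 with fry and 0 with an estimated correlation. The 6 include the TGF-beta list, which had missed camera. With fry p53 targets and mitosis (0.0796 each), replication (0.0714), sterol synthesis (0.115) and NRF2 targets (0.0949) missed the threshold for the site. The cause was not tested. The list DNA replication, metastatic knockdown, turned direction with the line-number term (adjusted p = 0.910); the cause was not tested. No paired analysis was possible because the line numbers are not shared between groups.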

Other observations

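The tests of the mitosis genes and of whether the chromosome shifts come with the knockdown were chosen after the result was seen. In the primary pair, which has no replicate check, several lists stood apart from random lists of the same size and expression. Members of a list can move together, so the percentiles are descriptions and not tests. NRF2 targets had a median log2 ratio of 0.30, at percentile 100 among random lists, while 8 of 18 fell in the metastatic lines. Immediate early genes had a median of 0.63 and squamous basal genes of 0.36, both at percentile 100, and integrins of 0.34, at percentile 99.8. Mesenchymal genes had a median of -0.25, at percentile 0.745, and 6 of 17 also fell in the metastatic lines. Whether the knockdown differences differ was tested by gene only, and no gene passed in edgeR.

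Among all 56 splits of the 8 metastatic lines into 5 and 3, only 1, the real one with 2634 genes, gave as many. That is the smallest share 56 splits can give. The highest other split gave 2097 and set lines 376, 377 and 378 against the rest. This points to a structure by line number that the labels do not name. The real split sets the highest line numbers apart, so the splits cannot tell the knockdown from line order. For the count of lists, 8 of 56 splits passed as many as the real 8, with 15 the highest, so chance is not excluded for that count.

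The fall of mitosis genes is not accounted for by depth, since 24 members were called lower with all libraries thinned to the smallest total. Nor did all cell cycle genes move alike, since the mean of mitosis genes minus that of replication genes differed by -0.658 on the log2 scale, shTrp53 minus shCtrl (exact permutation p = 0.0179, 2-sided, the smallest these lines can give). Birc5 minus the median of the other 25 mitosis genes differed by -0.319, shTrp53 minus shCtrl (exact permutation p = 0.0357, 2-sided). This value was 1.08 in shCtrl line 383 and 1.06 in shTrp53 line 387. No other member was tested in this way, so whether Birc5 fell beyond the list stays a hypothesis from the same data.

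Genes of 2 chromosomes, the one that carries Ocln (451 tested genes) and the one that carries Cdh1 (654), were higher as a whole in all 3 shTrp53 metastatic lines than in all 5 shCtrl metastatic lines, by medians of 0.33 and 0.31 on the log2 scale relative to all genes (camera adjusted p = 3.65e-08 over 20 chromosomes for each, 0.0386 and 0.0321 with an estimated correlation). GC content and expression level do not account for it, since both medians were at percentile 100 of 10000 matched sets, nor do a few strong neighbours, since 100% and 90.6% of blocks of 20 neighbouring genes were higher, against 42.8% elsewhere. In the primary pair, which has no replicates, the median relative to all genes was 0.17 for the second, over 0.5 of its shift, and 0.0311 for the first. For neither can a shift that comes with the knockdown be told apart from a difference between the lines. A difference in copies of these chromosomes was not tested here. Another chromosome, with 560 tested genes, was lower, by a median of -0.22 relative to all genes (20 genes rose and 114 fell, camera adjusted p = 0.000883, adjusted p = 0.363 with an estimated correlation), and was not weighed further. Outside the chromosomes that carry Ocln and Cdh1, 2282 of the 2634 genes were called.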
